A study of Homo sapiens with 12 samples.

How the data were processed

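RNA from HEK293T cells, wild type or CRAF knockout, serum starved or EGF activated, had been sequenced in 12 libraries, 3 per group. Replicate numbers were taken from the sample labels. The authors deposited 1 table of 61562 features, 60675 with Ensembl identifiers and 887 without, kept here. Per the file headers it holds raw read counts, which the analysis used. The submitters' notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1; the sources used here give no strand setting, genome build or annotation release. Because use of strand is not stated, values of genes that overlap another gene on the other strand are uncertain. Of the Ensembl identifiers, 57055 (94.0%) are in GENCODE release 29 on GRCh38, and 95.2% of those have the same coordinates, so positions are given on that build. The authors' FPKM values, per the file headers, divide counts by a gene length and by the library's summed gene counts. Recomputed from the counts and the length column, they agreed for 9.3 to 11.4% of the genes with at least 50 counts in a library, with a median ratio of 2.02 to 2.071, so they were not used in the tests. The authors' log2 fold changes and the deposited adjusted p-value of each comparison were set beside the results here.

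Library totals ran from 15770662 to 23579963 counts. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a filter on low counts (filterByExpr, minimum count 10) that left 19793 features, and a mean for each of the 4 groups over all 12 libraries. Groups were compared with the quasi-likelihood F test, two-sided, at a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold. Comparisons were knockout against wild type without and with EGF, EGF against serum starvation in each genotype, and the interaction. Standard errors are the log2 fold change divided by the square root of F. Normalised counts are given as CPM, a rate of the library's scaled total, and use the same scaling. Tested on simulated data with this design and depth, 4-fold changes were found for 92 to 94% of genes in the pairwise comparisons, 2-fold changes for 74 to 80%, 1.5-fold changes for 44 to 60% and 1.25-fold changes for 20 to 44%. In the interaction these were 88, 66, 38 and 15%, and false calls were 0.04 to 0.06% of genes. Each pairwise comparison held 50 changed genes per fold, and no simulated library was made to stand apart. These shares may thus not apply where a large part of all genes differ, as between the genotypes.

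The design, the tests, the rule for naming genes, 28 gene lists and most alternatives were fixed before the data were examined. The lists cover the EGF response and RAF signalling, proliferation, cell death, metabolism, stress, cell identity, RNA composition and markers of other cell types. Named genes are ARAF and BRAF; the 6 largest rises and falls among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap; up to 3 called members per list, or 2 for lists of RNA composition and other cell types; and FOS, EGR1, DUSP6 and SPRY4 for EGF. Some genes are not reported here. Lists were tested with camera of limma 3.58.1, preset correlation 0.01, two-sided and Benjamini-Hochberg adjusted within each comparison. Beside it stand camera with an estimated correlation and fry. Of the list calls, 0 without EGF and 0 with EGF between genotypes, 2 for EGF in wild type, 1 for EGF in the knockout and 1 for the interaction were also made with an estimated correlation. The median, mean and test had the same sign in each called list; 21 results that were not called had a median or mean of another sign than the test.

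After genes of some chromosomes were seen to move together, genes were ordered by position, and the median log2 fold change of windows of about 50 genes was compared with the 99.9th percentile over 1000 shuffles of gene positions. Each gene was also tested against the median of its 50 neighbours. Tested on simulated data, centring lowered calls of 270 genes that only shared a region's shift from 66.7 to 1.5%. A term for the 4 libraries that hold immunoglobulin reads was added after seeing the data, as were marker lists for 9 cell types. Alternatives were DESeq2 size factors and upper-quartile factors in the same test, DESeq2 1.42.0, limma-trend, other filters on low counts, a minimum of 2-fold, a fit of only the compared groups, replicate number as a block, and each library left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the windows and figures.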

Results

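RNA sequencing counted the transcripts of HEK293T cells, a human embryonic kidney cell line, that were wild type or lacked C-Raf, labelled CRAF-/-. C-Raf is a protein kinase that carries signals from RAS to MEK and ERK. Cells of both genotypes were serum starved or activated with epidermal growth factor (EGF), whose receptor activates RAS, with 3 libraries in each of the 4 groups. The sample labels used here name neither the dose and duration of EGF nor the lesion in the knockout. They also do not say whether the knockout cells are a single clone or several. Differences between genotypes, in level or in EGF response, thus cannot be told apart from differences between clones. The gene counts summed to 23579963, 21684332 and 18930297 in wild-type serum-starved replicates 1, 2 and 3 and to 19859545, 15770662 and 18869102 in the wild-type EGF replicates. They summed to 16359606, 16783791 and 16939229 in the knockout serum-starved replicates and to 20808000, 17283416 and 20980281 in the knockout EGF replicates. Genotype separated the libraries along the component that held 54.7% of the variance. The median standard deviation of log2 CPM (counts scaled to a common total by edgeR's cpm) between replicates was 0.101 in the wild-type EGF group and 0.058 to 0.067 in the other 3 groups. Wild-type EGF replicate 3 stood apart from replicates 1 and 2 (chi-square per gene 10.934 and 7.386, against 1.395 to 2.502 between the other replicates of a group).

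Transcripts of immunoglobulin genes, which plasma cells make, were found in 4 libraries. Summed over 159 immunoglobulin genes and JCHAIN, they reached 183.5, 169.0 and 167.7 CPM in the wild-type serum-starved libraries and 163.4 CPM in wild-type EGF replicate 1. The other 8 libraries held 0.65 to 1.80 CPM. These transcripts differ between groups because of how the 4 libraries fall, so each comparison was also fitted with a term for them, a choice made after the data were seen. The term is set only by wild-type EGF replicate 1 against the other wild-type EGF libraries, as no other group is mixed. EGF against serum starvation in wild type then rests on wild-type EGF replicate 1 alone among the EGF libraries. The genotype comparison without EGF takes on a correction from these few libraries. A call that ends with the term may thus reflect lost precision, not RNA from plasma cells.

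The comparison of genotypes in serum-starved cells asks what differs in cells that lack C-Raf before EGF is added. ARAF, which encodes a related kinase, rose by 0.21 on the log2 scale in the knockout (SE 0.05, n = 3 per group, adjusted p = 0.00234), and BRAF did not pass the test at -0.05 (SE 0.06, adjusted p = 0.54). By camera with a preset correlation, the knockout cells held fewer transcripts of amino acid synthesis and stress genes, p53 targets, endoplasmic reticulum chaperones and ribosomal proteins, and more of glycolysis, fibroblast marker, histone and cholesterol synthesis genes. With an estimated correlation these lists had adjusted p of at least 0.123. Of 19793 genes tested, 8885 passed, 4476 higher and 4409 lower in the knockout, and 1450 of them differed by at least 2-fold, 997 higher and 453 lower.

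The largest rises among well-measured genes were in USP44, a deubiquitinase of the mitotic checkpoint, from 9.91 ± 0.882 to 132 ± 3.34 CPM (mean and SD), in CLSTN2, a calsyntenin of synapses, from 2.34 ± 0.698 to 29 ± 0.928 CPM, and in USP41. The genes GPR50, NTRK2, the receptor for brain-derived neurotrophic factor, and SKIDA1 rose by 2.68, 2.66 and 2.65 on the log2 scale (SE 0.07, 0.13 and 0.09). USP41 went from 0.0893 ± 0.112 to 20.8 ± 1.06 CPM. Because USP41 and USP18 are near-identical copies, the place of these reads is uncertain; USP18, looked up after the values were seen, was not called at -0.04 (SE 0.06, adjusted p = 0.644). CTSZ, a lysosomal protease, fell from 9.78 ± 0.845 to 0.603 ± 0.183 CPM (adjusted p = 1.02e-11). The other 5 of the 6 largest falls were in immunoglobulin genes and JCHAIN, which moved with the 4 libraries named above. Wild-type and knockout means were 52.4 and 0.0196 CPM for IGLC3, 41.1 and 0.0193 CPM for IGHG2, 19.8 and 0.0193 CPM for IGLC2 and 26.6 and 0.0774 CPM for JCHAIN. IGHA1 stood at 21 CPM in wild type. Immunoglobulin constant genes are near-identical copies, so their single values are uncertain.

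Of 20 ATF4 target genes, which serve amino acid supply and stress, 18 were lower and 0 higher (18 and 0 adjusted over the list alone). Examples are ALDH1L2 at -1.37 (SE 0.11) and SHMT2 at -0.79 (SE 0.07), both enzymes of mitochondrial folate metabolism, and SLC7A5, an amino acid transporter, at -0.96 (SE 0.07). The list passed camera at adjusted p = 9.06e-10, and had adjusted p = 0.309 with an estimated correlation. Of 19 p53 target genes, 13 were lower and 0 higher (13 and 0 adjusted over the list alone), among them CCNG1, a cyclin, at -0.83 (SE 0.04), AEN at -0.63 (SE 0.05) and the repair gene XPC at -0.67 (SE 0.07), with adjusted p = 8.29e-07, or adjusted p = 0.254 with an estimated correlation. Of 18 endoplasmic reticulum chaperone genes, 14 were lower and 0 higher (14 and 0 adjusted over the list alone), including XBP1 at -0.88 (SE 0.08) and DNAJC3 at -0.70 (SE 0.06), with adjusted p = 1.64e-05, or adjusted p = 0.317 with an estimated correlation. Ribosomal protein genes were lower in 22 and higher in 3 of 30 (23 and 3 adjusted over the list alone), with RPS12 at -0.83 (SE 0.04), and had adjusted p = 6.16e-07, or adjusted p = 0.398 with an estimated correlation. Nuclear genes of oxidative phosphorylation were lower in 11 and higher in 0 of 23 (11 and 0 adjusted over the list alone), with ATP5F1 at -0.37 (SE 0.04), and had adjusted p = 0.0171, or adjusted p = 0.309 with an estimated correlation.

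Glycolysis and hypoxia genes were higher in 16 and lower in 3 of 24 (16 and 3 adjusted over the list alone). NDRG1, a gene induced by low oxygen, rose by 2.33 (SE 0.08), from 44.4 ± 2.37 to 223 ± 20 CPM, BNIP3 by 0.72 (SE 0.05) and PFKFB3 by 0.88 (SE 0.05), and the list had adjusted p = 7.09e-07, or adjusted p = 0.123 with an estimated correlation. Cholesterol synthesis genes were higher in 11 and lower in 4 of 23 (11 and 5 adjusted over the list alone), with IDI1 at 1.10 (SE 0.05), INSIG1 at 0.64 (SE 0.04) and SQLE at 0.59 (SE 0.05). That list had adjusted p = 0.00698, or adjusted p = 0.309 with an estimated correlation. Replication-dependent histone genes were higher in 8 and lower in 0 of 11 (9 and 0 adjusted over the list alone), with HIST1H1C at 1.23 (SE 0.10), and had adjusted p = 4.03e-05, or adjusted p = 0.123 with an estimated correlation. Histone genes resemble one another, so single members are uncertain. The share of counts in long noncoding and antisense genes was also higher, at least 1.955% in the knockout and at most 1.734% in the wild-type serum-starved libraries, as was that in features without Ensembl identifiers, at least 0.297% and at most 0.241%. Fibroblast markers rose in 4 and fell in 1 of 5 (4 and 1 adjusted over the list alone), with COL1A1, a collagen, at 1.39 (SE 0.09) and LUM at 1.53 (SE 0.21), and had adjusted p = 0.00112, or adjusted p = 0.123 with an estimated correlation. Mesenchymal genes, which share 3 members with other lists, rose in 9 and fell in 2 of 18 (9 and 3 adjusted over the list alone). SPARC stood at 0.86 (SE 0.08) and SNAI1, a transcription factor, at -2.93 (SE 0.20). The list had adjusted p = 0.0408, or adjusted p = 0.309 with an estimated correlation, 0.0507 without wild-type serum-starved replicate 1 and 0.121 without replicate 3. Neuronal genes rose in 7 and fell in 3 of 16 (10 and 4 adjusted over the list alone), with the neurofilament genes NEFL at 1.19 (SE 0.08) and NEFM at 0.93 (SE 0.07), and had adjusted p = 0.0389, or adjusted p = 0.254 with an estimated correlation.

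Lists closer to the RAF pathway moved in both directions. Of 29 RAS-RAF-MEK-ERK pathway components, 8 were higher and 10 lower (8 and 11 adjusted over the list alone, list adjusted p = 0.137). MAPK3, which encodes ERK, was at -1.04 (SE 0.06) and RPS6KA2, a kinase downstream of ERK, at -1.71 (SE 0.10). ERK feedback inhibitors were higher in 3 and lower in 4 of 16 (3 and 4 adjusted over the list alone, list adjusted p = 0.984), with SPRY1 at 1.32 (SE 0.08) and DUSP2 at -1.76 (SE 0.21). The MEK/ERK output signature was higher in 2 and lower in 3 of 10 (2 and 3 adjusted over the list alone, list adjusted p = 0.618), with ETV5 at -1.71 (SE 0.26). Immediate-early genes were higher in 7 and lower in 5 of 27 (7 and 6 adjusted over the list alone, list adjusted p = 0.535), with MYC at 0.64 (SE 0.06) and NR4A3 at 1.40 (SE 0.14). The remaining lists did not pass either. Higher and lower members were 6 and 2 of 15 YAP and SRF target genes, 4 and 4 of 14 AP-1 and invasion genes, 4 and 7 of 22 G1/S genes, 5 and 5 of 20 G2/M genes, 2 and 7 of 15 BCL2 family genes and 3 and 8 of 14 heat shock genes. They were 8 and 2 of 18 interferon-stimulated genes, 3 and 3 of 14 epithelial genes, 8 and 1 of 17 kidney developmental genes and 1 and 6 of 13 mitochondrially encoded genes. Of the markers of other cell types, 1 rose and 3 fell of 7 blood cell markers, 3 rose and 0 fell of 5 squamous and glandular carcinoma markers, and 0 of 10 hepatocyte markers had enough counts to be tested. Adjusted over the list alone, the counts in these 12 tested lists were the same or higher by at most 1 in each direction.

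Genes of some chromosome regions shifted together. Chromosome 16 was lower along its length (median -0.57 over 942 genes, 624 of them called lower), as were 6 from 110.8 Mb (-0.39) and 7 from 54.8 to 82.4 Mb (-0.59). Chromosome 17 from 28.3 Mb (0.39 over 905 genes), 9 from 41.0 Mb (0.38 over 628 genes) and 10 up to 23.2 Mb (0.36) were higher. Of 384 windows of about 50 neighbouring genes, 72 lay beyond the limit that shuffled gene positions gave, against at most 3 in any of 1000 shuffles. The 3402 genes inside the 66 windows that lay beyond it with EGF too supplied 2135 of the 8885 calls. Set against the median of its 50 neighbouring genes, MAPK3 stood at -0.38, RPS6KA2 at -1.27, SLC7A5 at -0.38, COL1A1 at 1.04, IDI1 at 0.68 and PFKFB3 at 0.48, each still past the test. In that setting 7945 genes were called, 6507 of them shared with the 8885, the mesenchymal list ended at adjusted p = 0.154, the other 10 called lists stayed, and the RAS-RAF-MEK-ERK list came to adjusted p = 0.0305.

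**Figure D1:**
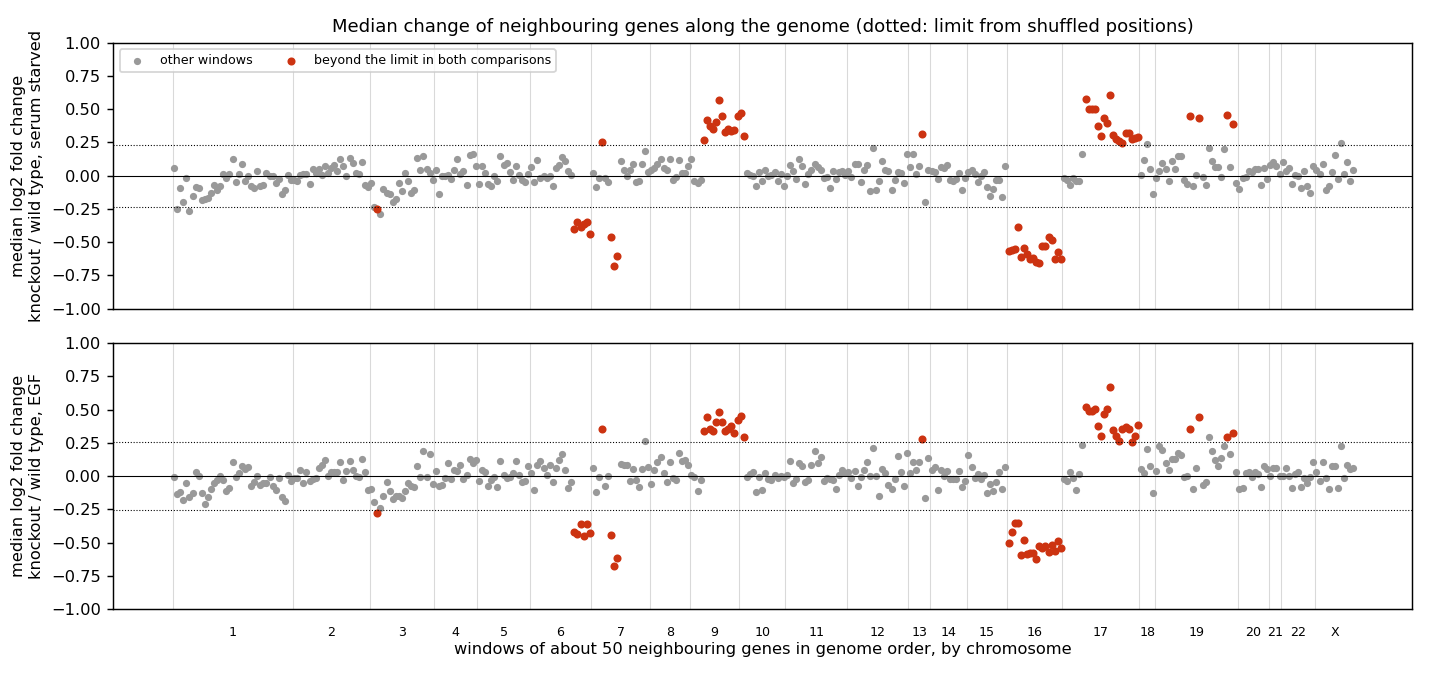
Median log2 fold change of knockout over wild type (vertical axis) in windows of about 50 neighbouring genes in genome order (horizontal axis), without EGF (upper panel) and with EGF (lower panel). The 66 red windows lay beyond the dotted limit of 0.233 (upper) or 0.257 (lower) in both.

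These tests were edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and their p-values measure only the spread between these libraries, as the labels do not say whether replicates were separate cultures. With a term for the 4 libraries that hold immunoglobulin reads, 4078 genes were called, 3731 of them shared with the 8885, and 6 lists. As the wild-type EGF libraries alone set the term, part of this fall may be lost precision. The lists that lost their call were endoplasmic reticulum chaperones, oxidative phosphorylation, ribosomal protein, neuronal and mesenchymal genes (adjusted p = 0.0633, 0.0633, 0.0502, 0.0889 and 0.191). Of the genes named above, USP41 (3.45, adjusted p = 0.945) and the immunoglobulin genes and JCHAIN lost theirs. USP41 held 0 CPM in wild-type EGF replicate 1, and the named immunoglobulin genes and JCHAIN at most 0.05 CPM in replicates 2 and 3. Their calls thus ended through near-zero counts in the libraries that set the term, and this loss tests nothing.

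With EGF, the comparison of genotypes asks what differs between EGF-activated cells. ARAF rose by 0.30 on the log2 scale in the knockout (SE 0.05, n = 3 per group, adjusted p = 7.67e-05) and BRAF was at 0.04 (SE 0.06, adjusted p = 0.629). By camera with a preset correlation, histone, mesenchymal and immediate-early genes were higher in the knockout, and ATF4 targets, p53 targets and heat shock genes were lower. With an estimated correlation these lists had adjusted p of at least 0.053. Of 19793 genes, 9128 passed, 4703 higher and 4425 lower, and 1516 of them differed by at least 2-fold, 1084 higher and 432 lower. Of these calls, 3525 were higher and 3423 lower in both genotype comparisons, against 1063.5 and 985.7 for independent lists, and 28 went opposite ways.

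Among the largest rises were USP41, at 21.1 ± 1.55 CPM in the knockout, with the doubt about its copy given above, USP44 at 3.73 (SE 0.07), CLSTN2 at 3.65 (SE 0.14), GPR50 at 2.70 (SE 0.07) and NTRK2 at 2.70 (SE 0.14). RN7SK, the small nuclear RNA that holds back transcription elongation, rose from 0.546 ± 0.129 to 25.7 ± 7.02 CPM. Its level varied widely between serum-starved libraries of the same group, from 0.79 to 9.67 CPM in wild type and from 1.65 to 10.92 CPM in the knockout. CTSZ fell by 4.07 (SE 0.20), the homeobox gene UNCX by 3.57 (SE 0.14), the costimulatory receptor gene TNFRSF9 by 3.15 (SE 0.21), the transcription factor gene SALL3 by 2.63 (SE 0.14), HLA-DPA1, which encodes a chain of major histocompatibility complex class II, by 2.58 (SE 0.15) and TCEAL3 by 2.55 (SE 0.17).

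All 11 replication-dependent histone genes tested were higher (11 adjusted over the list alone), with HIST1H1C at 1.63 (SE 0.10) and HIST1H2BD at 1.44 (SE 0.13). The list had adjusted p = 3.13e-06, or adjusted p = 0.053 with an estimated correlation. The share of counts in long noncoding and antisense genes was at least 1.705% in the knockout EGF libraries and at most 1.561% in the wild-type ones, and that in features without Ensembl identifiers at least 0.254% and at most 0.22%. The histone list was fixed as a list of RNA composition, and what moved it and these shares was not tested. Fibroblast markers were higher in 4 and lower in 0 of 5 (4 and 1 adjusted over the list alone), and mesenchymal genes higher in 11 and lower in 1 of 18 (11 and 1 adjusted over the list alone). COL1A1 was at 1.52 (SE 0.09), COL3A1 at 1.33 (SE 0.14) and VIM, vimentin, at 0.54 (SE 0.05). The lists had adjusted p = 0.000144 and 0.000156, or adjusted p = 0.053 and 0.148 with an estimated correlation. Immediate-early genes were higher in 15 and lower in 2 of 27 (16 and 3 adjusted over the list alone), with CYR61 at 0.84 (SE 0.09) and JUN at 0.34 (SE 0.05), and had adjusted p = 0.0111, or adjusted p = 0.383 with an estimated correlation. Neuronal genes were higher in 6 and lower in 1 of 16 (6 and 1 adjusted over the list alone) and kidney developmental genes higher in 9 and lower in 1 of 17 (10 and 1 adjusted over the list alone). NEFL stood at 1.07 (SE 0.09) and LRP2, an endocytic receptor of the kidney tubule, at 1.54 (SE 0.12). Adjusted p was 0.0457 and 0.0275, or adjusted p = 0.298 for both with an estimated correlation, and the neuronal list lost its call without wild-type EGF replicate 1 (adjusted p = 0.0601) and with the term for immunoglobulin reads (adjusted p = 0.064).

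ATF4 targets were lower in 16 and higher in 0 of 20 (16 and 0 adjusted over the list alone), with SLC7A5 at -0.94 (SE 0.07), and p53 targets lower in 13 and higher in 0 of 19 (13 and 0 adjusted over the list alone), with RRM2B at -0.62 (SE 0.05). The lists had adjusted p = 4.17e-06 and 0.000105, or adjusted p = 0.399 and 0.298 with an estimated correlation. Heat shock genes were lower in 9 and higher in 1 of 14 (9 and 1 adjusted over the list alone), with HSPA8 at -0.40 (SE 0.06), and had adjusted p = 0.0275, or adjusted p = 0.298 with an estimated correlation. Endoplasmic reticulum chaperones were lower in 10 and higher in 3 of 18 (11 and 3 adjusted over the list alone) and ribosomal protein genes lower in 14 and higher in 6 of 30 (14 and 7 adjusted over the list alone). DNAJC3 was at -0.62 (SE 0.06) and RPS12 at -0.74 (SE 0.04). Adjusted p was 0.0283 and 0.0457, or adjusted p = 0.596 and 0.701 with an estimated correlation, 0.101 and 0.188 without wild-type EGF replicate 1 and 0.106 and 0.208 with the term for immunoglobulin reads. Ribosomal protein genes also lost their call without wild-type EGF replicate 2 (adjusted p = 0.0556) and knockout EGF replicate 3 (adjusted p = 0.0818). Glycolysis and hypoxia genes divided, with 8 higher and 8 lower of 24 (8 and 8 adjusted over the list alone), among them NDRG1 at 1.73 (SE 0.07). ETV5 at -1.39 (SE 0.21), RPS6KA2 at -1.70 (SE 0.10) and DUSP2 at -1.94 (SE 0.19) were lower here as well. The other lists were not called. Of the 384 windows, 68 lay beyond the limit, 66 of them with the same sign without EGF. The 3402 genes inside these 66 windows supplied 2167 of the 9128 calls.

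Against neighbouring genes, 8144 genes were called, 6691 of them shared with the 9128. All 11 called lists stayed, and the YAP and SRF, G2/M and epithelial lists came to adjusted p = 0.0231, 0.00895 and 0.0231.

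**Figure D2:**
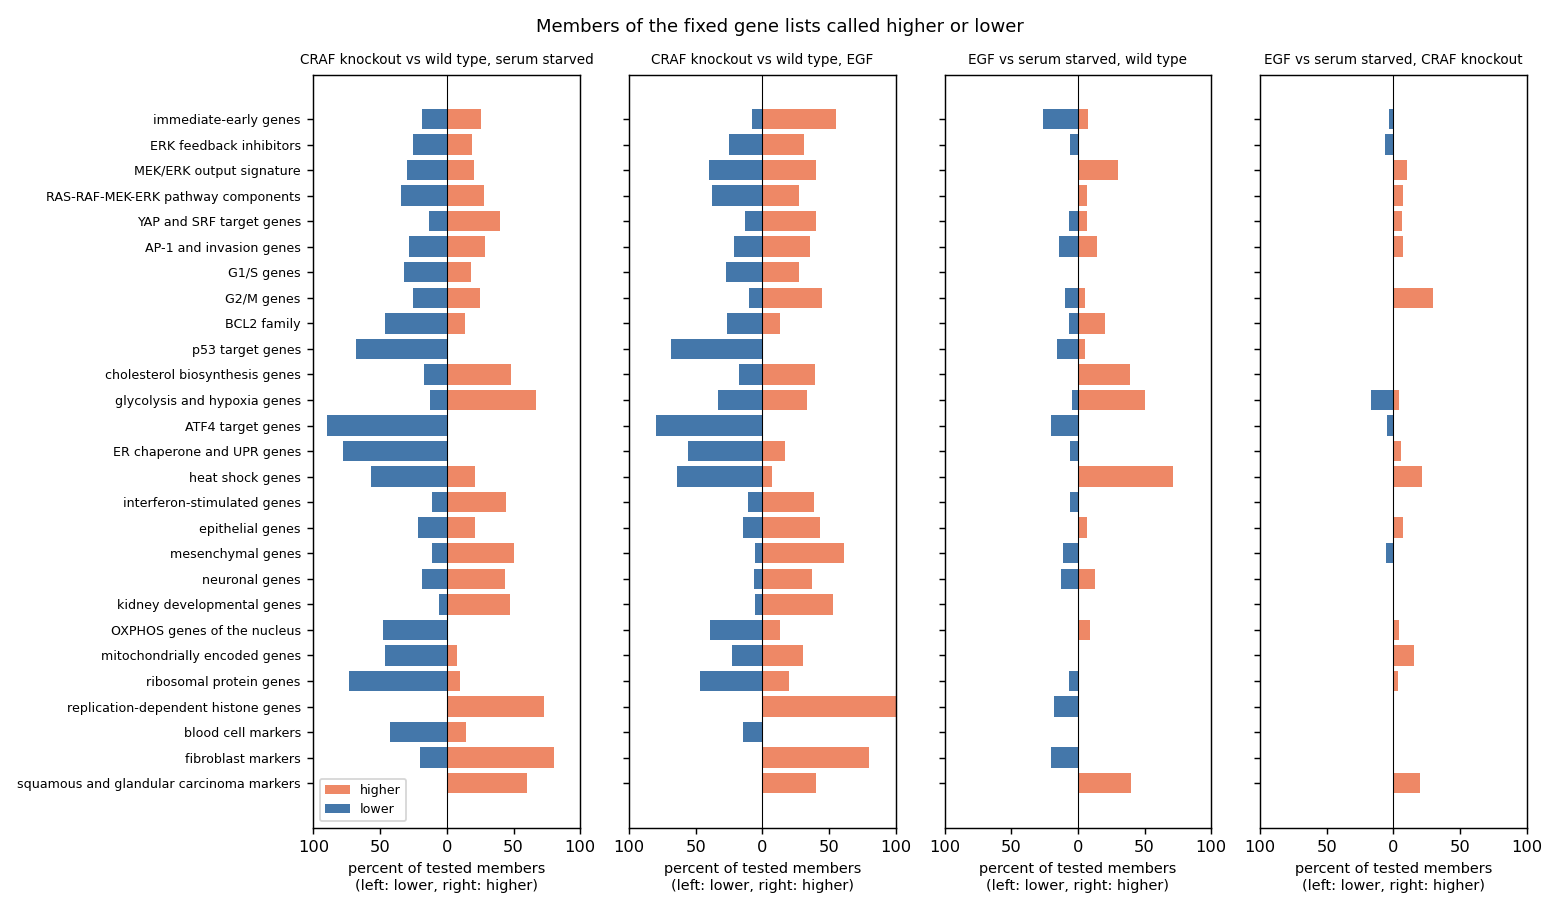
Percent of the tested members of each fixed gene list called higher (right of 0, orange) or lower (left of 0, blue) in each of 4 comparisons. Of the ATF4 targets, 18 of 20 were lower in the knockout without EGF and 16 of 20 with EGF, and of the heat shock genes 10 of 14 were higher with EGF in wild-type cells.

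EGF against serum starvation in wild-type cells shows how these cells responded to the growth factor. Chaperones of the heat shock response, cholesterol synthesis genes and glycolysis genes rose, while FOS, FOSB and other immediate-early genes, which growth factors induce within minutes, stood lower than in starved cells. Of these lists, heat shock and cholesterol synthesis genes also passed camera with an estimated correlation. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) fell by 1.5 on the log2 scale (SE 0.17, n = 3 per group, adjusted p = 2.37e-05), from 9.81 ± 1.18 to 3.5 ± 0.508 CPM, and was lower in each of the 3 EGF libraries than in any starved one. Of the other markers of ERK output, EGR1 did not pass at -0.37 (SE 0.12, adjusted p = 0.0582), although it did without wild-type serum-starved replicate 2 (adjusted p = 0.0158) or wild-type EGF replicate 3 (adjusted p = 0.015), with upper-quartile scaling (adjusted p = 0.0466) and without a filter on low counts (adjusted p = 0.0373). DUSP6 and SPRY4, at 0.562 and 0.364 CPM, did not pass either (adjusted p = 0.937 and 0.862). Of 19793 genes, 1376 passed, 739 higher and 637 lower with EGF, and 96 differed by at least 2-fold, 12 higher and 84 lower. The share of counts in long noncoding and antisense genes was at least 1.621% in the starved libraries and at most 1.561% with EGF. That in features without Ensembl identifiers was at least 0.226% and at most 0.22%, while mitochondrial shares overlapped.

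The largest falls were in SNAI1, from 21.9 ± 7.34 to 1.65 ± 0.255 CPM, and in ARC, a gene of neuronal activity, from 20.2 ± 1.22 to 4.2 ± 0.552 CPM. FOS, given above, the kinase gene SGK1 at -1.31 (SE 0.15), ARPIN, an inhibitor of actin branching, at -1.29 (SE 0.15) and GADD45B, a stress gene, at -1.26 (SE 0.11) followed. The largest rise was in ZCCHC12, a zinc finger transcriptional coactivator, from 27.4 ± 0.407 to 90.3 ± 7.84 CPM (log2 1.72, SE 0.07, adjusted p = 2.35e-12). TNFRSF12A rose by 0.64 (SE 0.11) and SYTL5 by 0.58 (SE 0.10).

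Heat shock genes rose in 10 and fell in 0 of 14 (14 and 0 adjusted over the list alone). HSPA1B went from 932 ± 47.6 to 1570 ± 116 CPM, and HSP90AA1 rose by 0.31 (SE 0.04). HSPA1A is a near-identical copy of HSPA1B, so how their reads divide is uncertain. The list had adjusted p = 2.28e-18, and adjusted p = 0.00251 with an estimated correlation. Cholesterol synthesis genes rose in 9 and fell in 0 of 23 (15 and 0 adjusted over the list alone), with INSIG1, which restrains the pathway, at 0.48 (SE 0.04), and had adjusted p = 5.21e-11, and adjusted p = 0.0378 with an estimated correlation. Glycolysis and hypoxia genes rose in 12 and fell in 1 of 24 (13 and 1 adjusted over the list alone), with the enolase gene ENO1 at 0.44 (SE 0.03), and had adjusted p = 1.27e-08, or adjusted p = 0.0676 with an estimated correlation. Immediate-early genes fell in 7 and rose in 2 of 27 (10 and 2 adjusted over the list alone). Besides FOS they include FOSB at -1.25 (SE 0.15) and CYR61 at -0.58 (SE 0.09), and the list had adjusted p = 2.01e-05, or adjusted p = 0.224 with an estimated correlation and adjusted p = 0.171 with the term for immunoglobulin reads. In the MEK/ERK output signature EPHA2 rose by 0.29 (SE 0.05), 3 higher and 0 lower of 10 (3 and 1 adjusted over the list alone, list adjusted p = 0.175, or 0.0126 without wild-type EGF replicate 2). ERK feedback inhibitors rose in 0 and fell in 1 of 16 (0 and 1 adjusted over the list alone, list adjusted p = 0.753). The lists of nuclear oxidative phosphorylation genes (higher), p53 targets, ATF4 targets, mesenchymal and ribosomal protein genes (lower) each had adjusted p = 0.0325, and histones (lower) had adjusted p = 0.0302. With an estimated correlation these had adjusted p = 0.517, 0.602, 0.781, 0.416, 0.781 and 0.416. They rested on few calls, such as CCNG1 at -0.28 (SE 0.04). Without wild-type EGF replicate 3, which stood apart, the oxidative phosphorylation, p53, ATF4, ribosomal protein and histone lists lost their call (adjusted p = 0.0648, 0.736, 0.212, 0.562 and 0.0656), as they did with the term for immunoglobulin reads (adjusted p = 0.101, 0.961, 0.212, 0.234 and 0.358); in both settings the direction of the ATF4 and ribosomal protein lists turned from lower to higher. Mesenchymal genes lost theirs without wild-type serum-starved replicates 1 or 2 (adjusted p = 0.0552 and 0.082) or wild-type EGF replicates 1 or 2 (adjusted p = 0.151 and 0.0794), and other lists without some of the same libraries.

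**Figure D3:**
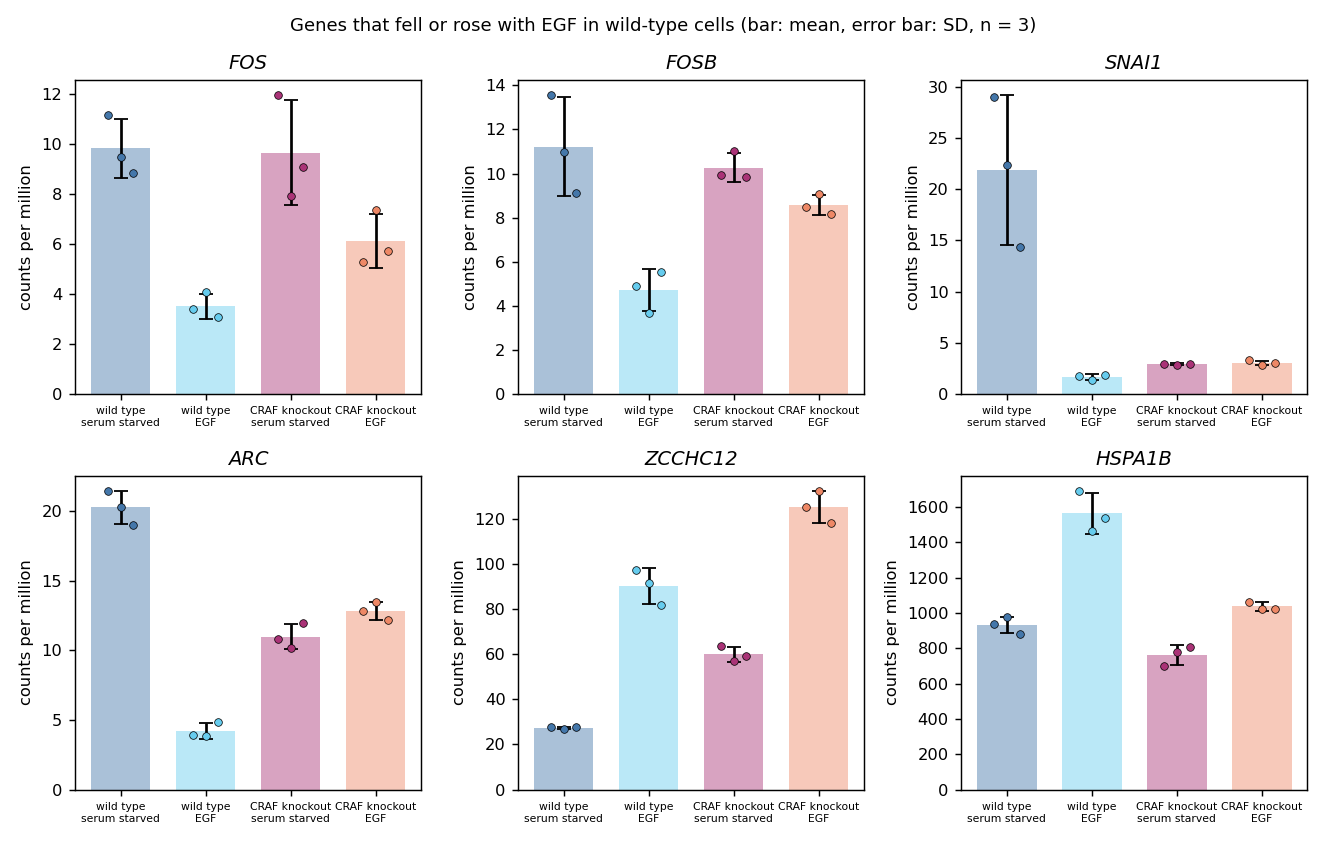
CPM of 6 genes in each library (points) with group means (bars) and SD (error bars, n = 3). FOS, FOSB, SNAI1 and ARC were lower with EGF in wild-type cells and ZCCHC12 and HSPA1B higher; ARC was at 11 ± 0.908 and 12.8 ± 0.678 CPM in the knockout.

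The count of genes rested on single libraries: it was 3560 without wild-type EGF replicate 3, and 906, 818 and 817 without wild-type serum-starved replicates 1, 2 and 3. It was 449 when only the 6 libraries compared were fitted, and the share of called genes that were higher, 53.7%, was 39.9% with upper-quartile scaling (517 higher, 778 lower) and 67.6% with DESeq2 (1075 higher, 516 lower); with the term for immunoglobulin reads, 1256 genes were called, 763 of them shared with the 1376.

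EGF against serum starvation in the knockout shows the response of these knockout cells. Some genes of mitosis and chaperones rose, and some genes induced by low oxygen fell. ZCCHC12 rose here too, from 59.9 ± 3.35 to 125 ± 7.28 CPM (log2 1.06, SE 0.06, n = 3 per group, adjusted p = 5.25e-09), as did HSPA1B, from 761 ± 57 to 1040 ± 23.1 CPM (adjusted p = 0.00038). FOS fell by 0.67 (SE 0.16, adjusted p = 0.0351), a call that ended without any 1 of the 6 knockout libraries (adjusted p = 0.0541 to 0.241), and EGR1 did not pass at 0.27 (SE 0.11, adjusted p = 0.259). Of 19793 genes, 329 passed, 252 higher and 77 lower, and 11 differed by at least 2-fold. The share of counts in long noncoding and antisense genes was at least 1.955% without EGF and at most 1.83% with it. That in features without Ensembl identifiers was at least 0.297% and at most 0.274%, and that in mitochondrial genes at most 2.69% and at least 2.75%. Between the EGF comparisons 120 genes rose in both and 24 fell in both, against 9.4 and 2.5 for independent lists, and 2 went opposite ways.

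G2/M genes rose in 6 and fell in 0 of 20 (9 and 0 adjusted over the list alone), with CDC20, an activator of mitotic exit, at 0.34 (SE 0.05), BUB1 at 0.21 (SE 0.04) and CCNB1 at 0.21 (SE 0.04). The list had adjusted p = 4.26e-11, or adjusted p = 0.0847 with an estimated correlation. Heat shock genes rose in 3 and fell in 0 of 14 (8 and 0 adjusted over the list alone), with BAG3 at 0.37 (SE 0.07), and had adjusted p = 3.98e-10, and adjusted p = 0.0202 with an estimated correlation. Glycolysis and hypoxia genes fell in 4 and rose in 1 of 24 (7 and 2 adjusted over the list alone), with PDK1 at -0.50 (SE 0.09), BNIP3 at -0.37 (SE 0.05) and PFKFB3 at -0.24 (SE 0.05), and had adjusted p = 4.32e-06, or adjusted p = 0.114 with an estimated correlation. BHLHE40 at -0.50 (SE 0.08), a transcription factor of the low-oxygen response, and MIR210HG at -0.51 (SE 0.12), the host RNA of miR-210, fell as well. Lists of oxidative phosphorylation, mitochondrially encoded and ribosomal protein genes had adjusted p = 1.1e-07, 4.22e-06 and 8.37e-08, with 1, 2 and 1 members called higher and 0 lower, and examples CYC1 at 0.19 (SE 0.04) and MT-ND2 at 0.20 (SE 0.04). With an estimated correlation they had adjusted p = 0.0847, 0.114 and 0.424. Cholesterol synthesis, chaperone, MEK/ERK output, AP-1 and epithelial lists were also higher, at adjusted p = 0.00023, 0.000197, 0.00854, 0.0114 and 0.0191, or adjusted p = 0.177, 0.424, 0.33, 0.204 and 0.292 with an estimated correlation, with 0, 1, 1, 1 and 1 members called. The member called of the epithelial list was KRT7, at 0.85 ± 0.207 CPM with EGF against 0.0196 ± 0.034 CPM. The epithelial list lost its call without knockout serum-starved replicate 2 (adjusted p = 0.0795), and the AP-1 list without that library (adjusted p = 0.0528) or knockout EGF replicate 2 (adjusted p = 0.0873). BUB1, CCNB1, BAG3, PDK1, PFKFB3, BHLHE40, MIR210HG, CYC1 and MT-ND2 lost their calls without knockout serum-starved replicate 1 (adjusted p = 0.0529 to 0.198) and without knockout EGF replicate 1 (adjusted p = 0.0568 to 0.161), and some of them without other knockout libraries.

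The count fell to 17, 40 and 60 without knockout serum-starved replicates 1, 2 and 3 and to 17, 55 and 67 without knockout EGF replicates 1, 2 and 3. Other fits called more genes, 746 with DESeq2 and 699 without a filter on low counts. The count was 1475 when only the 6 libraries compared were fitted and 618 with the term for immunoglobulin reads. No knockout library carries that term, so it can change these calls only through the spread estimated over all libraries. When only the 6 libraries compared were fitted, wild type had fewer calls, 449, than the knockout. The authors' deposited calls, 230 in wild type and 512 in the knockout, had that order too. DESeq2, with 1591 in wild type, kept the order of the reported fit.

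The interaction of genotype and EGF asks which genes responded to EGF differently in knockout and wild-type cells. Of 19793 genes, 65 passed, 50 with a more positive and 15 with a more negative response in the knockout. Among the former were 4 genes that fell with EGF in wild-type cells, SNAI1 with a difference of 3.79 (SE 0.35, adjusted p = 9.48e-06), ARC with 2.49 (SE 0.15, adjusted p = 1.06e-08), GADD45B with 1.37 (SE 0.16) and SGK1 with 1.32 (SE 0.22). In the knockout SNAI1 was already at 2.89 ± 0.0919 CPM without EGF. SGK1 and GADD45B were also low there, at 5.08 to 6.04 and 23.97 to 25.89 CPM. Wild-type cells held 11.97 to 18.04 and 38.92 to 58.26 CPM without EGF, and 4.9 to 6.5 and 18.69 to 23.17 CPM with it. ARC, at 10.16 to 11.96 CPM in the serum-starved knockout, lay between its wild-type levels without and with EGF. ZCCHC12, which rose in both genotypes, differed by -0.66 (SE 0.09), and the glycogen branching enzyme gene GBE1 by -0.77 (SE 0.11). FOS at 0.84 (SE 0.24, adjusted p = 0.185) and EGR1 at 0.64 (SE 0.16, adjusted p = 0.111) were not shown to differ, though EGR1 passed without wild-type serum-starved replicate 2 (adjusted p = 0.0285) or wild-type EGF replicate 3 (adjusted p = 0.00979), and both passed without a filter on low counts (adjusted p = 0.00984 and 0.0159).

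Glycolysis and hypoxia genes had a more negative response in the knockout, with 6 called of 24 (16 lower and 1 higher adjusted over the list alone). They include LDHA at -0.43 (SE 0.06), ENO1 at -0.30 (SE 0.04) and NDRG1 at -0.60 (SE 0.10), and the list had adjusted p = 8.53e-23, and adjusted p = 0.0091 with an estimated correlation. Immediate-early genes had a more positive response, with 3 called of 27 (7 higher and 0 lower adjusted over the list alone), namely FOSB at 0.99 (SE 0.21), CYR61 at 0.62 (SE 0.13) and IER5 at 0.51 (SE 0.09), and adjusted p = 7.47e-08, or adjusted p = 0.132 with an estimated correlation. These 3 genes lost their calls without wild-type serum-starved replicate 1, wild-type EGF replicate 2, knockout serum-starved replicates 1 or 3, or knockout EGF replicates 1 or 2 (adjusted p = 0.0536 to 0.168), and CYR61 and FOSB without others too. With the term for immunoglobulin reads they and NDRG1 were not called (adjusted p = 0.0759 to 0.159). In all, 13 lists were called, 10 with a more positive and 3 with a more negative response, and 1 of them with an estimated correlation.

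The count of 65 was 612 without wild-type EGF replicate 3, 131 without wild-type EGF replicate 1, 40 without wild-type EGF replicate 2 and 38 without wild-type serum-starved replicate 1. It was 43 and 36 without knockout serum-starved replicates 2 and 3, 37, 35 and 41 without knockout EGF replicates 1, 2 and 3, 102 with DESeq2 and 224 without a filter on low counts. With the term for immunoglobulin reads it was 62, of which 38 were shared with the 65.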

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

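The tests of the immediate-early genes with a term for immunoglobulin reads and of exchanged labels were chosen only after the result was seen. These results stand out because the response to EGF differed between knockout and wild-type cells by a test of the difference itself, the interaction in edgeR's quasi-likelihood test. It separated 65 of 19793 genes, 612 without wild-type EGF replicate 3, 131 without wild-type EGF replicate 1, and 35 to 43 without wild-type serum-starved replicate 1, wild-type EGF replicate 2, knockout serum-starved replicates 2 or 3, or any knockout EGF replicate. With the term for immunoglobulin reads 62 genes were called, 38 of them shared with the 65. The log2 difference, the knockout response minus the wild-type response, was 3.79 for SNAI1, 2.49 for ARC, 1.37 for GADD45B, 1.32 for SGK1 and 1.24 for IER5L. It was 0.51 for IER5, 0.62 for CYR61, 0.99 for FOSB, 0.25 for ATF4 and 0.30 for MT-ND2. It was -0.77 for GBE1, -0.69 for SYTL5, -0.66 for ZCCHC12, -0.60 for NDRG1, -0.43 for LDHA, -0.41 for SGMS2, -0.36 for INSIG1 and -0.30 for ENO1. RN7SK differed by 5.35, with libraries of the wild-type and knockout serum-starved groups between 0.794 and 10.9 CPM and those of the knockout EGF group between 21.6 and 33.8 CPM. With that term IER5, CYR61, FOSB, ATF4, NDRG1, SYTL5 and RN7SK lost their calls (adjusted p = 0.0702 to 0.159). IER5, CYR61, FOSB, ATF4, MT-ND2, SGMS2, SYTL5 and RN7SK lost theirs without knockout EGF replicate 2 (adjusted p = 0.0517 to 0.139), all of these but SYTL5 without wild-type serum-starved replicate 1 (adjusted p = 0.0575 to 0.333) and without wild-type EGF replicate 2 (adjusted p = 0.0601 to 0.14), and some of them without other libraries.

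Of the fixed lists, 10 had a more positive response in the knockout by camera, with adjusted p of 7.47e-08 for immediate-early genes, 0.033 for G1/S genes, 7.02e-06 for G2/M genes, 0.00162 for ATF4 targets, 9.15e-06 for endoplasmic reticulum chaperones, 0.000132 for mesenchymal genes, 0.000132 for mitochondrially encoded genes, 4.89e-12 for ribosomal protein genes, 0.0106 for histones and 0.0106 for blood cell markers. A more negative response was called for glycolysis and hypoxia genes at 8.53e-23, cholesterol synthesis genes at 0.000563 and heat shock genes at 0.000699. With an estimated correlation, glycolysis and hypoxia genes had adjusted p = 0.0091 and the other 12 lists adjusted p = 0.132 to 0.529. With the term for immunoglobulin reads G1/S genes, ATF4 targets, endoplasmic reticulum chaperones, ribosomal protein genes, histones and blood cell markers were not called (adjusted p = 0.0692 to 0.526), and the direction of ATF4 targets turned to more negative (adjusted p = 0.339). G1/S genes lost their call without 10 of the 12 libraries, all but wild-type serum-starved replicate 3 and wild-type EGF replicate 1 (adjusted p = 0.0506 to 0.291). ATF4 targets lost theirs without wild-type EGF replicate 3 or knockout serum-starved replicate 1 (adjusted p = 0.542, with the direction again turned, and 0.106), histones without wild-type serum-starved replicate 1 or wild-type EGF replicate 2 (adjusted p = 0.0835 and 0.0861) and blood cell markers without wild-type EGF replicate 3 (adjusted p = 0.0522).

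The real groups called 65 genes in the interaction, and 5 of 60 splits of the libraries within each genotype, the real one included, called as many. Chance is not excluded by this count, which cannot test it, since the other splits that reached 65 carry the EGF response of at least 1 genotype. The highest other split called 2133 genes. It exchanged the treatments of all knockout libraries, so its contrast adds the EGF responses of both genotypes. The others, with 299, 216 and 67 genes, kept the groups of 1 genotype whole and so carry its EGF response.

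Immediate-early genes were lower with EGF in wild-type cells, 7 of 27 in edgeR's test. A difference in library size is argued against, since 7 of the 7 stayed called and lower with every library thinned to the smallest total. An exchange of EGF and serum-starved labels in 1 genotype is argued against by a Pearson r of 0.289 between the responses of both genotypes. It was taken across 1559 genes, which are not independent replicates. The same exchange in both genotypes would leave r unchanged, so this test cannot address it. With a term for the 4 libraries that hold immunoglobulin reads, 5 of the 7 stayed lower with p adjusted over these 7, FOS at -1.55 and FOSB at -1.20 among them, while IER5 at -0.11 and KLF2 at -0.62 did not; with p adjusted over all genes 4 passed, while KLF4 had adjusted p = 0.0522 at -0.50, close to its -0.55 without the term. As a list, immediate-early genes had adjusted p = 0.171 with the term. For IER5 and KLF2, EGF cannot be told apart from whatever wild-type EGF replicate 1 shares with the serum-starved libraries. The fit with the term sets that replicate alone against the serum-starved libraries, and EGF replicates 2 and 3 serve only to estimate the term. EGF itself stays open as a biological explanation. Sampling after the early peak of these genes may be part of it, which the labels, naming no time, leave untested. Of the 7 genes, only FOS was also called lower with EGF in the knockout (-0.67), while the others stood at -0.26 to 0.23. Any other difference between the wild-type serum-starved and EGF libraries cannot be told apart from EGF here.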

How the results depend on the processing

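The term for the 4 libraries with immunoglobulin reads, the setting against neighbouring genes and the count outside shifted windows were chosen only after the data were seen. A minimum of 2-fold lowered the calls by construction, to 1450 and 1516 genes between genotypes without and with EGF, 96 for EGF in wild type, 11 for EGF in the knockout, 23 for the interaction, and 888 and 2 genes shared by the genotype and by the EGF comparisons. With an estimated correlation 0, 0, 2, 1 and 1 lists were called, and with fry, which asks another question, 22, 22, 4 and 5 (EGF in the knockout aside). With the term for immunoglobulin reads 4078 genes and 6 lists were called between genotypes without EGF and 4 lists for EGF in wild type. With it 618 genes were called for EGF in the knockout and 7 lists for the interaction. No knockout library carries the term, so the 618 can differ from the reported 329 only through the spread estimated over all libraries. DESeq2 called 746 genes for EGF in the knockout, 102 for the interaction and 358 in both EGF comparisons; without a filter on low counts the former were 699 and 224, and the cause was not tested. Fits of only the compared groups called 449 genes for EGF in wild type and 1475 in the knockout, each with a spread from its own 6 libraries. The reported fit, with a spread shared by all 12 libraries, called 1376 and 329, so the order reversed. The shared spread includes the wild-type EGF group, whose replicates varied most (median standard deviation of log2 CPM 0.101, against 0.058 to 0.067). Whether this accounts for the reversal was not tested. Replicate numbers did not pair the libraries (correlations of deviations -0.121 to 0.053, with 1 of 12 libraries closest to its own number); with a replicate block 128 genes were called for EGF in the knockout, 41 for the interaction and 55 in both EGF comparisons, and 8447, 8771 and 1070 in the other comparisons. Apart from single libraries left out, the remaining settings stayed within 1.5 times the reported count. Leaving out each library gave 7770 to 7888 genes and 10 to 11 lists between genotypes without EGF, 7955 to 9851 genes and 8 to 12 lists with EGF, 817 to 3560 genes and 4 to 11 lists for EGF in wild type, 17 to 67 genes and 9 to 12 lists for EGF in the knockout, and 35 to 612 genes and 10 to 15 lists for the interaction. For EGF in wild type the count was 906, 818 and 817 without wild-type serum-starved replicates 1, 2 and 3 and 3560 without wild-type EGF replicate 3, with 4, 6 and 6 lists without wild-type serum-starved replicates 1 and 2 and wild-type EGF replicate 3. For EGF in the knockout it was 17, 40 and 60 without knockout serum-starved replicates 1, 2 and 3 and 17, 55 and 67 without knockout EGF replicates 1, 2 and 3. For the interaction it was 38 without wild-type serum-starved replicate 1, 131, 40 and 612 without wild-type EGF replicates 1, 2 and 3, 43 and 36 without knockout serum-starved replicates 2 and 3, and 37, 35 and 41 without knockout EGF replicates 1, 2 and 3. Of 4809 alternative values for 303 named results, 4371 kept direction and side of the threshold, 419 lost the call, 10 gained it and 9 turned. With the term for immunoglobulin reads and no EGF these were IGHA1 at 0.02, IGLC3 at 1.67, IGHG2 at 2.04, IGLC2 at 1.99 and JCHAIN at 1.12. Against neighbouring genes, whose shared shift is taken out, they were GINS2 at 0.04 without and 0.16 with EGF, SALL1 at 0.16 without EGF and ALDOA at 0.06 with EGF. Of 1.5-fold changes at most 60% were found in data simulated with this number and depth of libraries. Those data held far fewer changed genes than were called between genotypes, so this share may not apply there.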

Other observations

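The tests of plasma cell markers, of the immunoglobulin level across groups and of copy number by windows were chosen only after the result was seen. Interferon-stimulated genes were not called as a list between genotypes (adjusted p = 0.0879 without and 0.121 with EGF), yet 8 and 7 of 18 were higher in the knockout and 2 and 2 lower. OAS3, an enzyme of the defence against viral RNA, was at 1.66 (SE 0.13) and 1.69 (SE 0.13), BST2, which holds back budding viruses, at 1.84 (SE 0.16) with EGF, and IFI44L at 1.86 (SE 0.22) and 1.90 (SE 0.22). LRP2, which encodes an endocytic receptor, was at 1.49 (SE 0.12) without EGF. The tight junction gene TJP3 was at 1.41 (SE 0.16) and 1.22 (SE 0.16).

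The G1/S and G2/M lists were not called between genotypes, and single cell cycle genes differed in either direction. CCNE1, a cyclin of entry into DNA replication, was at -0.76 (SE 0.07) without and -0.74 (SE 0.07) with EGF, and CCND2 at -0.73 (SE 0.08) with EGF. The proliferation marker MKI67 was at 0.26 (SE 0.04) and 0.44 (SE 0.04). PLK1, at -0.66 (SE 0.05) without EGF, lies on chromosome 16 and was at -0.07 against its neighbours. TOP2A, at 0.44 (SE 0.04), lies on chromosome 17 and was at 0.07. PMAIP1, a gene of the BCL2 family that favours cell death, was at -0.65 (SE 0.07) and -0.51 (SE 0.07).

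Genes lower or higher in the knockout lay together on chromosomes, with 72 windows without EGF and 68 with EGF beyond the limit, where shuffled positions gave at most 3 and 4. In the EGF comparison within the knockout, where genotype does not differ, 9 windows lay beyond a limit of 0.098, against at most 4, and within wild type 2 lay beyond 0.121, against at most 4. Bias by GC content or gene length is argued against, as 98.6% and 97.1% of the windows stayed beyond the limit after trends with both were removed. Library size is argued against too, as 91.7% of the windows shifted without EGF were shifted the same way with EGF, where the library totals overlapped. Without EGF each wild-type total, at least 18930297 counts, exceeded each knockout total, at most 16939229 counts. With EGF the totals were 15770662 to 19859545 counts in wild type and 17283416 to 20980281 counts in the knockout. A copy-number difference between the knockout and wild-type cells may account for the grouping, but the 72 windows restate the pattern and do not test it, and DNA was not analysed here. Whether such a difference, if present, arose with the loss of C-Raf or apart from it stays open, since these libraries hold no other line.

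Immunoglobulin transcripts marked the 3 wild-type serum-starved libraries and wild-type EGF replicate 1. Genotype or EGF treatment is argued against as the source, since the summed level was 163.4 CPM in wild-type EGF replicate 1 and at most 1.61 CPM in replicates 2 and 3. Of 9 plasma cell markers, with immunoglobulin genes and JCHAIN left out, 3 had their lowest value in the 4 libraries above their highest in the other 8, against 1 of 78 markers of 8 other cell types. The means in the 4 libraries were 3.75 CPM for MZB1, 2.28 CPM for POU2AF1 and 1.07 CPM for TNFRSF17, while PIM2 and DERL3 of that list were also present in the other 8 libraries, at 54.0 and 7.84 CPM. Reads or RNA from plasma cells may thus be present in these 4 libraries; no sort or gate is named in the labels, and the step at which they entered was not tested.

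Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real groups called 8885, 9128, 1376 and 329 genes in the 4 pairwise comparisons, 1 of 10 splits in each. The highest other split called 0 in each by edgeR. Every other split mixes the real groups, so their difference enters its spread, and a count of 0 there cannot test chance.

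The authors' deposited table called 7632 and 5645 genes between genotypes without and with EGF, 230 for EGF in wild type and 512 for EGF in the knockout. Of these, 97.1%, 99.2%, 98.7% and 58.2% were called here in the same direction. Pearson r between the log2 fold changes, across genes, was at least 0.998.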
